A study of Mus musculus with 18 samples.

How the data were processed

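RNA of fibroblasts sorted from mouse paws was sequenced in 18 libraries: naive unstimulated, naive with FGF2 (10 ng/mL), naive with OPN (50 ng/mL), naive with both, STIA unstimulated and STIA with OPN, with 3 libraries in each of the 6 groups and stimulation for 3 days. Per the labels total RNA was taken with a column kit, and a service provider made the libraries and sequenced them as paired reads on a NovaSeq X Plus. The antibodies and gates of the cell sort, the strandedness of the libraries and any batch or date are not given in the sources used here.

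The deposited table holds raw counts per gene and library, which the authors made by aligning reads with STAR and counting them with featureCounts on GRCm38 (mm10), with no normalisation. The versions of both tools, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The table also holds a Length column, which is the summed length of each gene's exons in bases and not a measurement. It was not used. Values were checked to be whole numbers. Of 32285 identifiers 32158 were matched to symbols of GENCODE mouse release M21, and 31954 of these had the same chromosome, start and end there; 127 identifiers without a symbol took 0.03% of counts. Loci are printed as the deposited table gives them.

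Library totals ran from 27527043 to 40357342 counts, and 24146 genes had at least 1 count. No pair of replicates was identical over 18 pairs, and chi-square per degree of freedom between replicates ran from 4.42 to 40.73. Same-numbered replicates were tested for pairing across groups: correlations of their deviations from the group mean ran from -0.104 to 0.199, and 2 of 45 pairs lay above 0.1, so replicate numbers were not used as a block in the model reported. The mitochondrial share was lowest in the library numbered 3 in 5 of 6 groups, and the block was run as an alternative.

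The model was fitted in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups (15072 genes), library sizes were scaled by TMM, and a no-intercept model with 1 mean per group was fitted by robust quasi-likelihood over all 18 libraries, so that all groups share 1 estimate of the spread (biological coefficient of variation 8%). The 10 comparisons were contrasts tested by the quasi-likelihood F test, two-sided, and called at a Benjamini-Hochberg adjusted p below 0.05. They comprised FGF2, OPN and both factors against unstimulated naive cells, STIA against naive cells, OPN against unstimulated STIA cells, both factors against FGF2 and against OPN, FGF2 against OPN, the interaction of FGF2 and OPN, and the difference of the OPN effect between STIA and naive cells. The SE of a log2 fold change is the fold change divided by the square root of its F statistic. Principal components used log2 CPM with a prior count of 2. Levels are CPM on TMM-scaled library sizes, except that markers of other cell types and the lowest-library levels of pan-fibroblast genes are CPM on plain totals. Acta1 and Myh11 in the comparison of STIA with naive cells are on TMM-scaled sizes.

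The groups, comparisons, tests, gene lists, naming rule and alternatives were fixed before the data were examined. The 32 gene lists were MAPK/ERK feedback and target genes, FGF ligands and receptors, osteopontin and its receptors, cell cycle, inflammatory mediators, interferon response, matrix degradation, structural extracellular matrix, contractile and TGF-beta target genes, synovial lining, synovial sublining and pan-fibroblast genes, osteogenic and chondrogenic, adipogenic, Wnt pathway, cholesterol synthesis, glycolysis and hypoxia, amino acid and integrated stress response, p53 and senescence, complement, secreted growth factors, macrophage-directed ligands, immediate early and mitochondrially encoded genes, and markers of macrophages, neutrophils and lymphocytes, endothelium, pericytes and smooth muscle, Schwann cells, skeletal muscle, keratinocytes and erythroid cells. Some genes stand in more than 1 list, such as Egr1, C3, Col1a1 and Spp1. The list named immediate early genes was fixed as dissociation and immediate early genes and also holds the heat-shock genes Hspa1a, Hspa1b and Dnajb1. Each list with at least 3 tested members was tested by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists within a comparison. The estimated correlation and fry were alternatives, and fry does not compare a list with other genes. Members were also adjusted over the list alone.

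Named genes followed a rule. In each of the first 5 comparisons named above, the 10 largest rises and the 10 largest falls were taken among genes with an adjusted p below 0.05, a mean of at least 5 CPM and no overlap between the libraries of the groups compared, a condition that chance meets for 10% of genes with 3 against 3 libraries. For the other comparisons it was 5 and 5, without the overlap condition for the interaction and the difference of the OPN effect. Up to 4 members of each called list or list with at least 3 called members were named by smallest adjusted p, as were Fgf2, Fgfr1, Spp1, Cd44, Itgav and called markers of other cell types. Predicted and clone-named genes were left out. The report prints levels in place of a fold for a gene whose mean lay at or near the floor of 3 counts in 1 of the groups. Fitted interaction values of such genes are given with that limit.

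Shared effects were counted per direction beside the product of the calls over the genes tested, and beside 20 simulated data sets in which unchanged groups were set against the same controls. The procedure was tested on simulated data: for OPN in STIA cells with 50 genes changed at each size, edgeR called 18 at 1.25-fold, 37 at 1.5-fold, 46 at 2-fold and 50 at 4-fold, and 10 of 14843 unchanged genes.

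The alternatives were DESeq2 size factors, library totals alone, no filter on low counts, a filter at 5 CPM in 3 libraries, the replicate number as a block, DESeq2 1.42.0, limma-voom, only the groups compared in the model, counts thinned to the smallest total, an adjusted p below 0.01 for shared genes, and leaving out each library in turn. Each model count was also set against other splits of the same libraries, 10 for a comparison of 3 with 3 libraries and 100 drawn for each of the interaction contrasts. Figures and tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

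Exons of some named genes overlap those of another gene, such as Ddit3 with Mars, Mest with Copg2, Shox2 with Rsrc1 and Junb with Prdx2, and Kng1 has a close paralog, so that part of their reads depends on the unstated counting settings.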

Results

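Gene-level RNA counts were compared in 18 libraries of fibroblasts sorted from the synovium of mouse paws. The cells came from naive mice or from mice with serum-transfer-induced arthritis (STIA), a joint inflammation set off by injecting serum of K/BxN mice. Naive cells were left unstimulated or received 10 ng/mL fibroblast growth factor 2 (FGF2, a mitogen for fibroblasts), 50 ng/mL osteopontin (OPN, a secreted ligand of integrins and CD44) or both for 3 days. STIA cells were left unstimulated or received OPN. Each of these 6 groups held 3 libraries. The labels do not say whether replicates came from separate mice or separate cultures, so each p-value measures the spread between these samples only. The time that unstimulated cells spent in culture is not given in the sources used here.

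Library totals ran from 27527043 to 40357342 counts, and between 18067 and 19131 genes had a count in each. By group the totals were 29232126 to 32385299 (naive unstimulated), 28784279 to 32160896 (FGF2), 30759870 to 40357342 (OPN), 27527043 to 36336001 (FGF2 plus OPN), 27678577 to 36910640 (STIA unstimulated) and 28199887 to 36649839 (STIA with OPN). A floor of 3 counts corresponded to 0.0743 to 0.109 CPM per library, where CPM is the gene's count scaled to a common library total, and this floor covers counting error only. Levels of other genes are means ± SD in CPM on the normalised library sizes over the 3 libraries of a group, and log2 fold changes are given ± SE from the edgeR quasi-likelihood model, with adjusted p-values after Benjamini-Hochberg correction over 15072 genes.

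The first principal component held 50.6% of the variance and the next held 22.0%. Fibroblast transcripts were found in every library, with Col1a1, a chain of type I collagen, at 3720 CPM or more, the intermediate filament gene Vim at 4700 CPM or more and the growth factor receptor gene Pdgfrb at 275 CPM or more. Other pan-fibroblast genes were low, such as Fap and Twist2 at 5.01 and 5.43 CPM in their lowest library. The fibroblast levels just given and those of markers of other cell types are CPM on plain library totals. Acta1 and Myh11 in the comparison of STIA with naive cells are on normalised library sizes. Among macrophage markers Cd14 averaged 5.85 CPM in unstimulated naive cells and 44.9 CPM with FGF2, while Ptprc, C1qa and Adgre1 stayed at 0.26 CPM or less in every group mean. FGF2 replicate 2 lay farther from its group than any other library, at a root mean square log2 distance of 0.416, against 0.294 to 0.363 for the others. Spp1 alone took 2.83% of its counts and 1.65% to 1.73% in the other FGF2 libraries.

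**Figure D1:**
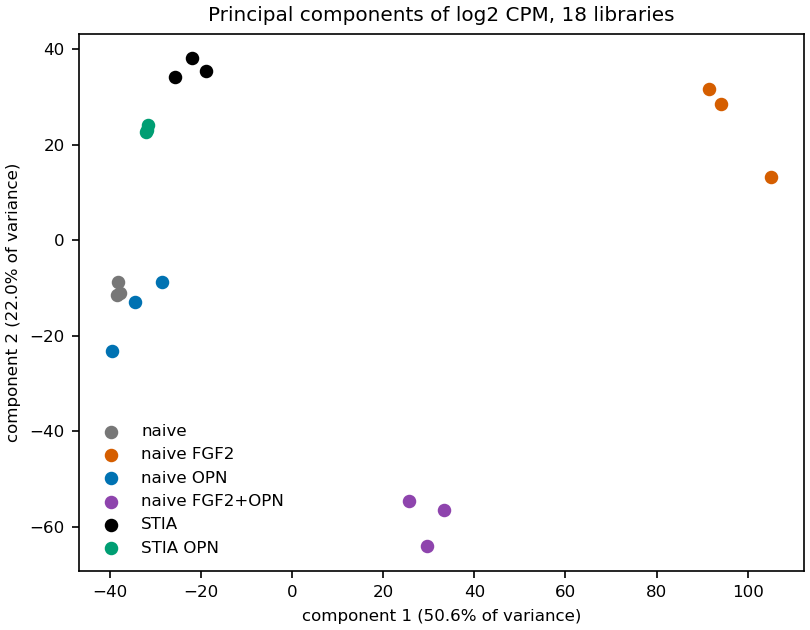
Principal components of log2 CPM for the 18 libraries, 1 point per library coloured by group. The first axis held 50.6% of the variance and the second 22.0%.

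What FGF2 did to naive fibroblasts was read against the unstimulated naive cells. Spp1, the gene of osteopontin itself, rose from 1422 ± 48.6 CPM to 20220 ± 6760 CPM (n = 3 each), a log2 fold change of 3.83 ± 0.16. Mmp10, a stromelysin that degrades matrix, stood at 0.091 ± 0.0417 CPM without and 148 ± 48.0 CPM with FGF2, and its relative Mmp3 rose from 22.1 ± 1.6 to 1113 ± 592 CPM. Col1a1 fell from 36970 ± 3310 to 4067 ± 330 CPM (log2 fold change -3.18 ± 0.12). Ptx3, a soluble pattern recognition protein, fell by 9.04 ± 0.44 and the neutrophil attractant Cxcl5 fell by 7.24 ± 0.39 on the log2 scale. Nptx1, a neuronal pentraxin, rose by 9.46 ± 0.24, from 0.31 ± 0.143 to 225 ± 44.3 CPM.

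Of 21 ERK feedback and target genes, 16 rose and 4 fell with FGF2 (camera adjusted p 1.51e-17). Among them the ERK inhibitors Spry4 and Spry2 rose by 4.32 ± 0.15 and 2.58 ± 0.07 (log2). Of 10 genes for osteopontin and its receptors, 8 rose and 2 fell (adjusted p 6e-06): the integrin chain Itgb3 rose by 4.45 ± 0.08 and the hyaluronan receptor Cd44 by 2.01 ± 0.12, whereas Itgb5 changed by -0.95 ± 0.06. Of 31 structural matrix genes, 3 rose and 25 fell (adjusted p 3.07e-18), Col5a1 by -2.97 ± 0.10. These 3 calls held with an estimated correlation between genes. Of 16 genes of the amino acid and integrated stress response, 1 rose and 14 fell (adjusted p 1.08e-12), among them Ddit3, a stress transcription factor, at -2.40 ± 0.08; this call was lost, at adjusted p = 0.104 with an estimated correlation. Sublining fibroblast genes split into 4 higher and 15 lower of 21 (adjusted p 4.26e-05, and adjusted p = 0.204 with an estimated correlation), with the chemokine Cxcl12 at -3.01 ± 0.12. Interferon response genes (1 higher, 13 lower of 20), contractile genes (2 higher, 12 lower of 20), cholesterol synthesis genes (1 higher, 14 lower of 20) and complement genes (3 higher, 7 lower of 10) were called at adjusted p 0.0191, 0.012, 0.00846 and 0.0134. With an estimated correlation their adjusted p = 0.704, 0.704, 0.704 and 0.377.

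The other lists were not called for FGF2. Their counts of higher and lower members were 8 and 6 of 16 for FGF ligands and receptors, 16 and 1 of 32 for cell cycle, 10 and 11 of 25 for inflammatory mediators, 9 and 12 of 26 for matrix degradation, 4 and 2 of 7 for lining fibroblast genes and 5 and 5 of 14 for pan-fibroblast genes. They were 6 and 14 of 20 for osteogenic and chondrogenic genes, 5 and 3 of 9 for adipogenic genes, 10 and 9 of 22 for the Wnt pathway, 4 and 13 of 22 for glycolysis and hypoxia, 8 and 2 of 12 for p53 and senescence, 10 and 11 of 23 for secreted growth factors, 11 and 8 of 21 for macrophage-directed ligands and 3 and 6 of 11 for immediate early genes. The pericyte marker Rgs5 averaged 2.16 CPM without and 42.0 CPM with FGF2. Markers of macrophages (3 and 3 of 6), endothelium (4 and 2 of 8), pericytes (1 and 5 of 7), Schwann cells (1 and 3 of 7) and skeletal muscle (0 and 1 of 4) were not called either. The 13 mitochondrially encoded genes had 0 members past the edgeR threshold, 1 at an unadjusted p below 0.05, 0 by DESeq2 and limma-voom, and 1 with the replicate number as a replicate block. Their share of counts was higher with FGF2 in each same-numbered pair of libraries, at 0.708% against 0.666%, 0.758% against 0.562% and 0.477% against 0.374%. Against the same naive libraries it was also higher in each pair with FGF2 plus OPN (0.692%, 0.867% and 0.455%). The same held for unstimulated STIA cells (0.694%, 0.587% and 0.383%). The labels do not link same-numbered libraries, and without pairing the ranges overlapped, at 0.374% to 0.666% unstimulated and 0.477% to 0.758% with FGF2. These comparisons all use the same naive libraries, so they are not independent of each other. Of the neutrophil and lymphocyte markers 1 of 2 tested genes rose and of the keratinocyte markers 1 of 1; no erythroid gene passed the filter. Adjusted over the list alone, the counts differed for cell cycle (15 and 1), inflammatory mediators (10 and 12), lining genes (5 and 2), cholesterol synthesis (2 and 15) and neutrophil and lymphocyte markers (1 and 1).

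**Figure D2:**
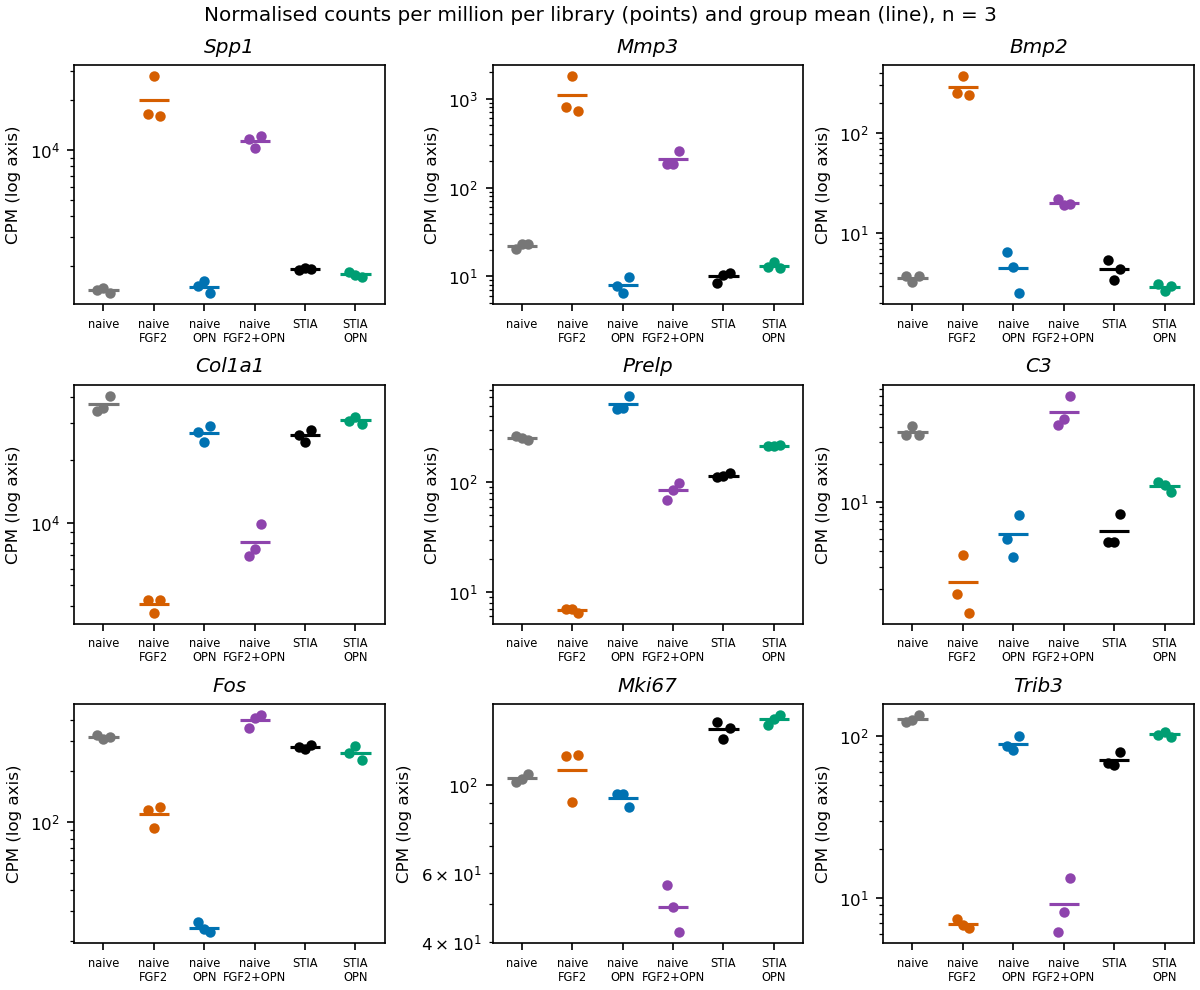
Levels of 9 genes in CPM on a log axis, 1 point per library, by group. Spp1 averaged 1422 CPM in unstimulated naive cells, 20220 CPM with FGF2 and 11420 CPM with FGF2 plus OPN, and Fos averaged 316 CPM in unstimulated naive cells and 23.9 CPM with OPN.

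In all, 8609 of 15072 genes passed for FGF2, 4379 higher and 4230 lower, and 1422 of them rose and 1578 fell at least 2-fold. With library totals alone 5233 were higher and 3535 lower. Without FGF2 replicate 2 the count was 8373.

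The comparison of OPN with unstimulated naive cells asked what osteopontin did on its own. Fos, a subunit of the AP-1 transcription factor, fell from 316 ± 10.2 to 23.9 ± 1.75 CPM (n = 3 each), a log2 fold change of -3.72 ± 0.10 (adjusted p 2.25e-16). Egr1, another immediate early gene, fell from 410 ± 14.5 to 84.1 ± 4.53 CPM, and C3, the central component of complement, fell from 36.2 ± 3.68 to 5.44 ± 2.13 CPM. The cytokine gene Il6 fell from 4.34 ± 0.419 to 0.372 ± 0.0831 CPM and the chemokine Cxcl1 from 46.7 ± 5.69 to 8.53 ± 0.961 CPM. Eln, the gene of elastin, rose by 2.17 ± 0.22 and Gdf10, a ligand of the BMP family, by 2.42 ± 0.20 on the log2 scale. Spp1 stood at 1495 ± 128 CPM with OPN and did not pass (log2 fold change 0.07 ± 0.15, adjusted p 0.744).

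Of 11 immediate early genes, 9 fell and 0 rose (camera adjusted p 3.58e-56), with Fosb at -3.53 ± 0.29 and the mRNA decay factor Zfp36 at -1.77 (log2). That list was fixed as dissociation and immediate early genes and also holds heat-shock genes, of which Hspa1a was among the 9. Of 20 osteogenic and chondrogenic genes, 8 rose and 1 fell (adjusted p 0.000646), including the growth factor Bmp4 at 1.23 and Col10a1, a collagen of hypertrophic cartilage, at 1.14. Both calls held with an estimated correlation. Of 22 glycolysis and hypoxia genes, 18 fell (adjusted p 6.42e-20), with Pdk1, a brake on pyruvate oxidation, at -0.96 ± 0.07; its adjusted p = 0.0546 with an estimated correlation. Of 25 inflammatory mediators, 2 rose and 13 fell (adjusted p 1.26e-07, and adjusted p = 0.119 with an estimated correlation). Integrated stress response genes (2 higher, 11 lower of 16) and ERK targets (4 higher, 8 lower of 21) leaned lower, at adjusted p 0.0112 and 9.51e-05, and at adjusted p = 0.743 and 0.245 with an estimated correlation. FGF ligands and receptors (8 higher, 2 lower of 16), Wnt pathway genes (8 higher, 1 lower of 22), cholesterol synthesis genes (9 higher, 1 lower of 20) and p53 and senescence genes (7 higher, 1 lower of 12) leaned higher, at adjusted p 0.0112, 0.014, 0.000404 and 0.00275. These 4 calls were lost, in that order at adjusted p = 0.0595, 0.0595, 0.696 and 0.114 with an estimated correlation. Adjusted over the list alone, the called lists differed for ERK targets (4 and 9), inflammatory mediators (2 and 15), cholesterol synthesis (10 and 1) and p53 and senescence (8 and 1).

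For OPN in naive cells 4783 genes passed, 2291 higher and 2492 lower (2375 and 2300 with library totals alone), with 403 rising and 214 falling at least 2-fold. Of 13 mitochondrially encoded genes 1 was called higher and 2 lower with OPN, and 3 and 3 with the replicate number as a block. Among them mt-Co3 fell from 17.3 ± 2.51 to 8.39 ± 1.79 CPM, and mt-Nd6 stood at 123 ± 34.1 without and 235 ± 14.6 CPM with OPN, a call that did not hold in every setting. The non-coding RNA Bc1 rose from 7.65 ± 1.19 to 35.7 ± 0.461 CPM. Among macrophage markers Lyz2 averaged 3.75 CPM in unstimulated and 9.8 CPM in OPN samples. In the same order Cd14 averaged 5.85 and 3.58 CPM and Csf1r 2.84 and 3.07 CPM. The labels give no date or batch within which immediate early genes of the 3 OPN libraries could be compared with those of the other groups.

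FGF2 plus OPN was set against unstimulated cells for the joint effect of both factors. Spp1 rose to 11420 ± 947 CPM (log2 fold change 3.01 ± 0.16), and Fos stood at 398 ± 35.4 CPM against 316 ± 10.2 CPM without stimulation. Trib3, a pseudokinase induced by the transcription factor ATF4, fell from 128 ± 6.7 to 9.22 ± 3.68 CPM (-3.80 ± 0.19). Mki67, a marker of proliferating cells, fell from 104 ± 2.39 to 49.1 ± 6.8 CPM (-1.08 ± 0.09). Csf2rb, the shared receptor chain for GM-CSF and interleukin 3, rose from 0.572 to 12.9 ± 1.38 CPM, and Gdf10 rose from 1.69 ± 0.04 to 31.5 ± 2.81 CPM.

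All 16 genes of the integrated stress response fell (camera adjusted p 1.26e-32), and this call held with an estimated correlation. Among 32 cell cycle genes 31 fell (adjusted p 5.31e-14, and adjusted p = 0.255 with an estimated correlation), including the helicase subunit Mcm2 at -1.23. Of 31 structural matrix genes, 5 rose and 20 fell (adjusted p 4.54e-14, and adjusted p = 0.0502 with an estimated correlation), with Col1a1 at -2.20. ERK targets (15 higher, 4 lower of 21, adjusted p 5.45e-06), osteopontin and its receptors (5 higher, 0 lower of 10, adjusted p 0.00304) and adipogenic genes (5 higher, 2 lower of 9, adjusted p 0.00355) leaned higher, at adjusted p = 0.24, 0.0502 and 0.0502 with an estimated correlation. The adipogenic members that rose included the transcription factor Cebpa (1.49) and the lipase Lpl (2.15). Contractile genes (3 higher, 14 lower of 20, adjusted p 0.0101), macrophage-directed ligands (10 higher, 5 lower of 21, adjusted p 0.00359) and immediate early genes (6 higher, 1 lower of 11, adjusted p 0.0116) were also called. These 3 calls were lost, at adjusted p = 0.652, 0.255 and 0.317 with an estimated correlation. Among markers of other cell types, from unstimulated to joint samples, the pericyte genes Rgs5, Abcc9 and Kcnj8 averaged 2.16 and 41.3, 1.51 and 8.66, and 0.23 and 1.72 CPM, and Cd14 averaged 5.85 and 15.5 CPM. The other tested pericyte markers Cspg4, Mcam, Notch3 and Myh11 averaged 260 and 158, 20.6 and 18.2, 22.3 and 24.1, and 2.04 and 1.07 CPM. The list of pericyte markers was not called. The called lists that differed when adjusted over the list alone were matrix (5 and 22), contractile (3 and 15) and adipogenic genes (6 and 2).

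For the joint treatment 7513 genes passed, 3573 higher and 3940 lower, with 1082 rising and 675 falling at least 2-fold. With library totals alone the median log2 fold change of all genes was 0.131, against -0.01 with TMM scaling, and the counts were 5253 higher and 2414 lower genes.

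OPN on top of FGF2 was tested by comparing the joint treatment with FGF2 alone. Mmp10 stood at 3.16 ± 0.482 CPM against 148 ± 48.0 CPM with FGF2 alone (log2 fold change -5.54 ± 0.22), and the growth factor gene Bmp2 at 20.2 ± 1.65 against 285 ± 72.9 CPM (-3.82 ± 0.22). Spp1 was lower by a log2 fold change of -0.82 ± 0.15 (adjusted p 9.08e-05). Ptx3 stood at 87.9 ± 34.8 against 1.15 ± 0.39 CPM, and Comp, a cartilage matrix protein, at 1679 ± 250 against 84.9 ± 22.1 CPM. The epithelial cytokine gene Tslp stood at 2.20 ± 0.192 against 68.8 ± 47.0 CPM.

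Of 21 ERK targets 3 were higher and 18 lower than with FGF2 alone (camera adjusted p 3.97e-12, and adjusted p = 0.0763 with an estimated correlation), with Spry4 at -3.12. All 32 cell cycle genes were lower (2.6e-15), and osteopontin and its receptors had 2 higher and 8 lower of 10 (0.00146), at adjusted p = 0.202 and 0.0763 with an estimated correlation. Higher members prevailed among structural matrix genes (25 higher, 2 lower of 31, adjusted p 2.24e-06), sublining genes (15 and 2 of 21, 2.05e-07), complement genes (9 and 0 of 10, 3.8e-06), interferon response genes (17 and 1 of 20, 5.33e-05), immediate early genes (6 and 3 of 11, 0.00016), pericyte markers (4 and 1 of 7, 0.0226) and adipogenic genes (6 and 3 of 9, 0.0473). None of these 7 calls held: adjusted p = 0.202 for matrix, 0.0966 for sublining, 0.0763 for complement, 0.229 for interferon, 0.133 for immediate early genes, 0.0973 for pericyte markers and 0.133 for adipogenic genes with an estimated correlation. Sublining genes had 17 higher and 2 lower members adjusted over the list alone, and the other called lists had the same counts.

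In this comparison 8804 genes passed, 4108 higher and 4696 lower (4743 and 3960 with library totals alone), of which 1512 and 1041 changed at least 2-fold.

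**Figure D3:**
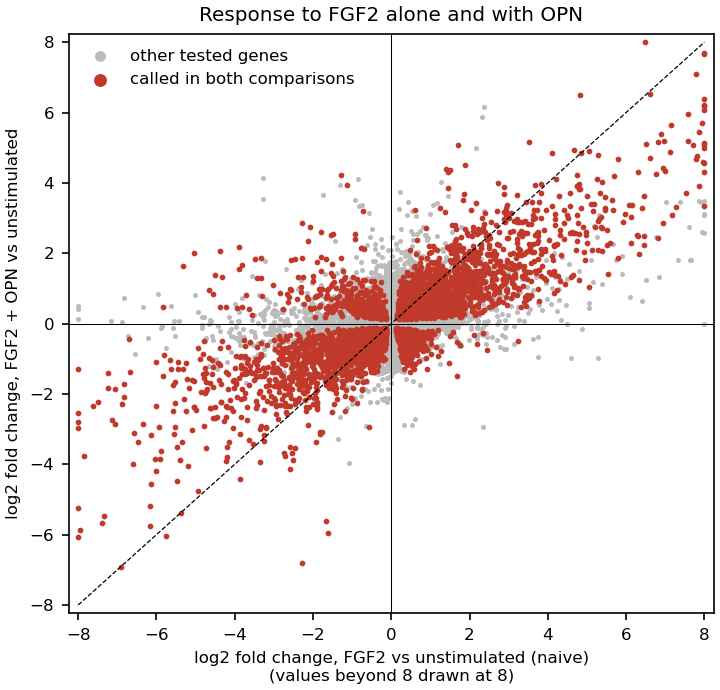
Log2 fold changes of genes against unstimulated naive cells, FGF2 alone on the horizontal and FGF2 plus OPN on the vertical axis, 1 point per gene, values beyond 8 drawn at 8, dashed line at equal change. Of 3000 genes that changed at least 2-fold with FGF2, 2274 were called against FGF2 alone in the direction of the unstimulated level. Picking genes by a large FGF2 change favours a smaller second value.

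FGF2 on top of OPN was tested against OPN alone. Mmp3 stood at 209 ± 40.5 CPM with both factors and 8.06 ± 1.74 CPM with OPN (log2 fold change 4.71 ± 0.34), and Fos was higher by 4.05. Spp1 was higher by 2.93, whereas Eln was lower by a log2 fold change of -4.13 and Col8a2, a collagen of basement membranes, by -4.57. Asns, the enzyme that makes asparagine, was lower at -1.92.

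Of 11 immediate early genes 10 were higher and 0 lower (camera adjusted p 2.36e-30), set against OPN libraries whose handling at harvest cannot be told apart from their group. ERK targets had 17 higher and 2 lower of 21 (1.27e-11), stress response genes 2 higher and 14 lower of 16 (3.91e-20) and adipogenic genes 6 higher and 2 lower of 9 (0.00332), and these 4 calls held with an estimated correlation. Cell cycle genes (0 higher, 28 lower of 32, adjusted p 1.37e-08), structural matrix genes (6 and 20 of 31, 1.37e-08), contractile genes (2 and 16 of 20, 0.00266), cholesterol synthesis genes (0 and 14 of 20, 0.000216), inflammatory mediators (14 and 3 of 25, 0.0154), glycolysis genes (17 and 3 of 22, 5.77e-05) and macrophage-directed ligands (11 and 4 of 21, 0.0154) did not hold. Their adjusted p = 0.445, 0.174, 0.538, 0.516, 0.523, 0.445 and 0.445 with an estimated correlation, in that order. Adjusted over the list alone, the called lists differed for inflammatory mediators (16 and 3), contractile (2 and 17), cholesterol (0 and 15) and glycolysis genes (18 and 3).

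Here 8522 genes passed, 4079 higher and 4443 lower, of which 1128 and 857 changed at least 2-fold. With library totals alone the median log2 fold change was 0.114, against -0.013 with TMM scaling, and the counts were 5433 higher and 3060 lower genes.

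The direct comparison of FGF2 with OPN, in which the unstimulated controls cancel, set the factors apart. Col8a2 was lower with FGF2 by a log2 fold change of -8.66, Ptx3 by -8.54 and the Wnt pathway gene Lgr5 by -8.50, while Nptx1 was higher by 7.72. The endothelial proteoglycan gene Esm1 stood at 26.0 ± 7.25 CPM with FGF2 and 0.114 ± 0.105 CPM with OPN. ERK targets (19 higher, 1 lower of 21, camera adjusted p 9.39e-25) and osteopontin and its receptors (6 and 2 of 10, 0.000396) were higher with FGF2, and both calls held with an estimated correlation. Immediate early genes (10 and 0 of 11, 2.15e-07) and cell cycle genes (23 and 2 of 32, 0.0255) were higher as well, at adjusted p = 0.0515 and 0.778 with an estimated correlation. For immediate early genes, handling of the OPN libraries at harvest cannot be told apart from the group. Lower with FGF2 were interferon (0 and 13 of 20, 0.00708), matrix (4 and 23 of 31, 2.64e-14), contractile (2 and 16 of 20, 0.00324), sublining (4 and 15 of 21, 0.000573), cholesterol (0 and 16 of 20, 1.25e-05), stress response (2 and 14 of 16, 9.78e-09) and complement genes (2 and 8 of 10, 0.0117). Their adjusted p = 0.539, 0.0769, 0.539, 0.269, 0.477, 0.196 and 0.319 with an estimated correlation. The Wnt pathway (9 and 8 of 22) was called lower at adjusted p 0.0411, with a mean log2 fold change of -0.83 and a median of 0.01, and adjusted p = 0.196 with an estimated correlation. Cell cycle (24 and 2) and matrix genes (4 and 24) differed among the called lists when adjusted over the list alone. In all 9278 genes passed, 4745 higher and 4533 lower with FGF2 (5375 and 3965 with library totals alone), of which 1441 and 1718 changed at least 2-fold, and the count was 9026 without FGF2 replicate 2.

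The interaction of FGF2 and OPN asked whether the joint effect departed from the sum of the single effects on the log2 scale. A positive value means that OPN raised a gene more, or lowered it less, in FGF2-treated than in untreated cells. C3 had an interaction of 7.31, Cxcl5 of 7.85 and the acute-phase gene Hp of 7.43, while the cannabinoid receptor gene Cnr1 had -6.43 and Serpinb2, a plasminogen activator inhibitor, -5.69. Immediate early genes (9 positive, 1 negative of 11, camera adjusted p 2.86e-25) and osteopontin and its receptors (2 and 8 of 10, 0.000186) kept their call with an estimated correlation. The immediate early values rest in part on the low OPN libraries. Fos averaged 23.9 CPM there, against 316 CPM unstimulated, 111 CPM with FGF2 and 398 CPM with both. Handling of the OPN libraries at harvest cannot be told apart from the group. Positive values prevailed for inflammatory mediators (12 and 7 of 25, 0.0079), interferon (15 and 1 of 20, 0.00178), matrix (23 and 2 of 31, 6.47e-07), sublining (15 and 2 of 21, 1.4e-07), glycolysis (18 and 1 of 22, 1.51e-07), complement (8 and 0 of 10, 3.12e-05) and pericyte genes (4 and 0 of 7, 0.0164), at adjusted p = 0.431, 0.396, 0.236, 0.0978, 0.236, 0.0978 and 0.0978 with an estimated correlation. Negative values prevailed for ERK targets (4 and 16 of 21, 9.28e-05), cell cycle (0 and 32 of 32, 1.52e-09) and p53 genes (2 and 8 of 12, 0.0183), at adjusted p = 0.274, 0.346 and 0.236 with an estimated correlation. Inflammatory mediators (12 and 9) and matrix genes (23 and 3), adjusted over the list alone, differed among the called lists. The interaction passed for 7723 genes, 3627 positive and 4096 negative, and with library totals alone 3955 were positive and 3613 negative.

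Unstimulated STIA and unstimulated naive fibroblasts were compared for what the arthritic joint left in the cells. Cck, the gene of the peptide hormone cholecystokinin, stood at 36.1 ± 1.47 CPM in STIA and 2.39 ± 0.345 CPM in naive cells (n = 3 each), a log2 fold change of 3.91 ± 0.27. Acta1, a sarcomeric actin, stood at 65.3 ± 8.71 against 6.30 ± 1.12 CPM, and the phosphatase gene Dusp4, a feedback inhibitor of ERK signalling, at 28.1 ± 1.88 against 5.92 ± 0.623 CPM. Scara5, a ferritin receptor, was lower by a log2 fold change of -4.61 ± 0.45, the Wnt modulator Sfrp2 by -3.19 ± 0.36 and C3 by -2.64 ± 0.33. Other skeletal muscle markers stayed low, with the intermediate filament gene Des at 2.34 CPM in STIA and 2.4 CPM in naive cells. Spp1 stood at 1915 ± 29.6 CPM in STIA and 1422 ± 48.6 CPM in naive cells.

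All 32 cell cycle genes were higher in STIA (camera adjusted p 3.75e-14, and adjusted p = 0.24 with an estimated correlation), the replication clamp gene Pcna by 0.50 and the cyclin gene Ccne1 by 0.68. Of 10 genes for osteopontin and its receptors 7 were higher and 1 lower (8.9e-08), with the integrin chain Itga5 at 1.09 and Cd44 at 1.20, and this call held with an estimated correlation. Contractile genes had 16 higher and 2 lower of 20 (4.99e-10, and adjusted p = 0.182 with an estimated correlation), including the tropomyosin genes Tpm1 (0.96) and Tpm2 (1.23). The smooth muscle genes Myh11, Lmod1 and Actg2 averaged 2.10, 8.52 and 20.9 CPM in naive and 9.42, 41.3 and 95.5 CPM in STIA cells. ERK targets (15 and 0 of 21, 4.99e-10), cholesterol synthesis genes (15 and 0 of 20, 1.07e-05) and secreted growth factors (10 and 7 of 23, 0.0322) leaned higher, at adjusted p = 0.0943, 0.401 and 0.347 with an estimated correlation. Lower members prevailed among complement (1 higher, 9 lower of 10, 2.19e-05), sublining (2 and 13 of 21, 6.48e-06), interferon (0 and 12 of 20, 0.000379), matrix (5 and 18 of 31, 0.00916), osteogenic and chondrogenic (2 and 10 of 20, 0.00625) and adipogenic genes (1 and 5 of 9, 0.00916). These 6 calls were lost, at adjusted p = 0.0943 for complement, 0.0943 for sublining, 0.388 for interferon, 0.506 for matrix, 0.0943 for osteogenic and 0.0943 for adipogenic genes with an estimated correlation. Adjusted over the list alone, the called lists differed for ERK targets (16 and 0), contractile (17 and 2), sublining (3 and 13), cholesterol (16 and 0) and growth factor genes (11 and 7).

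Between the sources of cells 5550 genes passed, 2810 higher and 2740 lower in STIA (2950 and 2564 with library totals alone), with 350 higher and 496 lower at least 2-fold.

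OPN in STIA fibroblasts was compared with unstimulated STIA cells. Prelp, a proteoglycan of connective tissue, stood at 215 ± 3.33 CPM with OPN and 115 ± 5.83 CPM without (n = 3 each), a log2 fold change of 0.90 ± 0.11 (adjusted p 0.000435). The matrix protein gene Thbs4 rose from 651 ± 57.9 to 1338 ± 59.1 CPM (adjusted p 0.000768) and Rspo3, an enhancer of Wnt signalling, from 13.5 ± 1.84 to 28.1 ± 0.977 CPM (adjusted p 0.000946). Plac8 fell from 7.38 ± 0.863 to 3.10 ± 0.283 CPM (adjusted p 0.00226) and Dusp4 from 28.1 ± 1.88 to 16.1 ± 1.15 CPM (adjusted p 0.00327). Spp1 (log2 fold change -0.11, adjusted p 0.801) and Cd44 (-0.33, adjusted p 0.157) did not pass.

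Sublining genes had 3 higher and 0 lower of 21 (camera adjusted p 5.62e-09), Schwann cell markers 3 and 0 of 7 (1.25e-05) and osteopontin and its receptors 0 and 2 of 10 (0.000678), and these 3 calls held with an estimated correlation. The Schwann cell marker Cdh19 averaged 8.93 CPM without and 14.4 CPM with OPN. Of 31 structural matrix genes 7 rose (1.38e-10), with Col15a1, a collagen of basement membrane zones, at 0.76 ± 0.10; adjusted p = 0.126 with an estimated correlation. Inflammatory mediators (1 and 0 of 25, 0.00527), glycolysis (3 and 1 of 22, 0.00177), stress response (1 and 0 of 16, 0.00133) and complement genes (0 and 1 of 10, 0.00766, median log2 fold change 0.43) were called higher, at adjusted p = 0.449, 0.449, 0.449 and 0.418 with an estimated correlation. ERK targets (0 and 2 of 21, 0.000455) and contractile genes (0 and 2 of 20, 5.78e-05) were called lower, at adjusted p = 0.421 and 0.449 with an estimated correlation. For 3 called lists 0 members passed the edgeR threshold. Cell cycle (camera 0.000222, median -0.13) had 3 lower members at an unadjusted p below 0.05 and 0 by DESeq2 and limma-voom; interferon (4.02e-05, median 0.34) had 5 higher at an unadjusted p, 2 by DESeq2 and 0 by limma-voom; cholesterol (0.00664, median -0.11) had 4 lower at an unadjusted p and 0 by DESeq2 and limma-voom. These calls were lost at adjusted p = 0.545, 0.418 and 0.545 with an estimated correlation. Adjusted over the list alone, the counts of higher and lower members were 11 and 1 for sublining, 5 and 0 for Schwann, 1 and 5 for osteopontin and its receptors, 13 and 1 for matrix, 2 and 0 for inflammatory, 5 and 1 for glycolysis, 3 and 0 for stress response, 4 and 1 for complement, 0 and 4 for ERK and 0 and 4 for contractile genes.

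For OPN in STIA cells 327 genes passed, 174 higher and 153 lower (170 and 175 with library totals alone, 167 and 186 with DESeq2 size factors), with 17 rising and 17 falling at least 2-fold; 2187 had an unadjusted p below 0.05. The count was 626 by DESeq2, 948 with no filter on low counts and 1367 with only these 6 libraries in the model, and it fell to 38, 81 and 218 without STIA unstimulated replicates 1, 2 and 3 and to 76, 44 and 112 without STIA OPN replicates 1, 2 and 3. The calls of Prelp, Thbs4, Rspo3, Col15a1, Plac8 and Dusp4 held in each of these settings.

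The difference of the OPN effect between STIA and naive fibroblasts was tested directly. Fos had a difference of 3.61 (log2, STIA minus naive), C3 of 3.95, Cxcl1 of 3.12 and the nuclear receptor gene Nr4a1 of 3.27, while Cck had -3.32. Immediate early genes had 8 positive and 1 negative of 11 (camera adjusted p 8.43e-39), which held with an estimated correlation. Handling of the naive OPN libraries at harvest cannot be told apart from this difference. Positive values prevailed for glycolysis (16 and 0 of 22, 2.01e-19), inflammatory (12 and 1 of 25, 6.4e-09), matrix (13 and 4 of 31, 4.77e-05), sublining (10 and 2 of 21, 0.000938), stress response (10 and 1 of 16, 0.00045) and Schwann cell genes (5 and 1 of 7, 0.0118), at adjusted p = 0.0686, 0.0908, 0.294, 0.207, 0.352 and 0.15 with an estimated correlation. Negative values prevailed for FGF ligands and receptors (2 and 7 of 16, 0.00961), osteopontin and its receptors (0 and 4 of 10, 0.00318), contractile (1 and 6 of 20, 0.0118), osteogenic (0 and 5 of 20, 0.00898), cholesterol (1 and 8 of 20, 3.16e-05) and p53 genes (1 and 5 of 12, 0.00318), at adjusted p = 0.0686, 0.0686, 0.568, 0.0908, 0.37 and 0.108 with an estimated correlation. Among the called lists the counts adjusted over the list alone differed for FGF (2 and 8), osteopontin (1 and 4), inflammatory (15 and 2), contractile (1 and 7), sublining (11 and 4), cholesterol (1 and 9), glycolysis (19 and 0), stress response (11 and 1) and Schwann genes (5 and 2). In all 3364 genes passed, 1776 positive and 1588 negative, against 1556 and 1744 with library totals alone and 1645 and 1683 with DESeq2 size factors.

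Changes shared between comparisons were counted against the same unstimulated naive controls. FGF2 and STIA shared 1526 genes higher and 1660 lower in both, with 674 in opposite directions, against 816 and 769 for independent calls in the same and 796 and 789 in opposite directions. FGF2 and OPN shared 952 higher and 1070 lower, with 1204 opposite, against 666 and 699 in the same and 724 and 643 in opposite directions. FGF2 and the joint treatment shared 2077 and 2051 with 900 opposite (1038 and 1106, 1145 and 1003), OPN and the joint treatment 840 and 927 with 1012 opposite (543 and 651, 599 and 591), and OPN and STIA 741 and 871 with 656 opposite (427 and 453, 416 and 465). Across genes, which are not independent replicates, r was 0.50 for FGF2 and STIA, 0.26 for FGF2 and OPN, 0.64 for FGF2 and the joint treatment, 0.30 for OPN and the joint treatment and 0.32 for OPN and STIA. In 20 simulated data sets unchanged groups gave r of 0.51, 0.53, 0.52, 0.53 and 0.52 from the shared controls alone, while the covariances were 0.401, 0.181, 0.708, 0.134 and 0.102 against 0.037 or 0.038 in the simulations. With the 3 controls parted between the comparisons, in 6 ways and on log2 CPM with a prior count of 2, r across genes was 0.41 to 0.44 for FGF2 and STIA, 0.15 to 0.18 for FGF2 and OPN, 0.56 to 0.60 for FGF2 and the joint treatment, 0.15 to 0.19 for OPN and the joint treatment and 0.14 to 0.19 for OPN and STIA. For FGF2 and STIA 3 of these partings were planned before their result, and all others were chosen after the values above were seen.

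The OPN effects in naive and STIA fibroblasts, which share no library, had 24 genes higher and 17 lower in both and 160 in opposite directions, against 26 and 25 for independent calls in the same and 23 and 29 in opposite directions (r -0.16 across genes). OPN in STIA cells and the difference between STIA and naive cells had 2 genes higher in both, 0 lower in both and 285 in opposite directions, against 32 and 28 for independent calls in the same and 29 and 32 in opposite directions (r -0.60, with -0.49 in simulations that share the unstimulated STIA libraries). Of those 285 genes 141 were higher in STIA and fell with OPN, such as Dusp4 and Cck, and 144 were lower and rose, such as Prelp and Thbs4. The call of Cck with OPN in STIA cells (adjusted p 0.00857) did not hold in every setting.

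**Figure D4:**
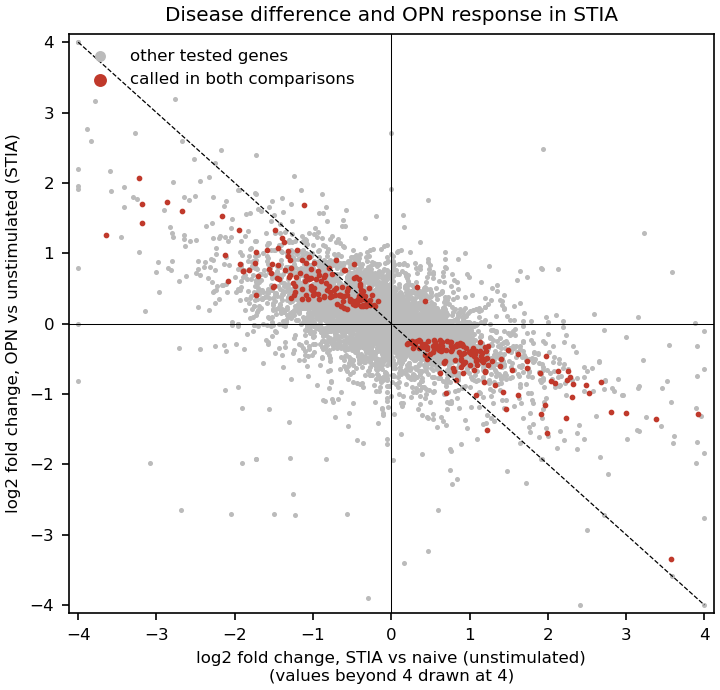
Log2 fold changes per gene, STIA against naive cells on the horizontal and OPN against unstimulated STIA cells on the vertical axis, values beyond 4 drawn at 4, dashed line at equal and opposite change. Genes called in both comparisons are red, and 285 of them moved in opposite directions.

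On GRCm38, Spp1 (ENSMUSG00000029304) lies on chromosome 5 from 104435118 to 104441050 and Mmp10 (ENSMUSG00000047562) on chromosome 9 from 7502352 to 7510240. Col1a1 (ENSMUSG00000001506) lies on chromosome 11 from 94936224 to 94953042 and Fos (ENSMUSG00000021250) on chromosome 12 from 85473890 to 85477273. C3 (ENSMUSG00000024164) spans 57203970 to 57228136 on chromosome 17 and Cck (ENSMUSG00000032532) spans 121489824 to 121495694 on chromosome 9. Scara5 (ENSMUSG00000022032) spans 65666403 to 65764826 on chromosome 14, as does Gdf10 (ENSMUSG00000021943) from 33923587 to 33937983. Prelp (ENSMUSG00000041577) is on chromosome 1 from 133910304 to 133921414, Thbs4 (ENSMUSG00000021702) on chromosome 13 from 92751590 to 92794818 and Trib3 (ENSMUSG00000032715) on chromosome 2 from 152337422 to 152344032.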

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

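The tests for a mixture of RNA, among them that of 1 common share of naive RNA and its 4 example genes, for immune cells and for handling at harvest, and the share of the FGF2 change kept in genes picked on other libraries, were chosen after the result they measure had been seen. The test of 1 common share was first run with SE from the 3 samples of each group, which put 41% and 41.7% of genes beyond 3 SE; its limits and the SE from the fitted model, used below, were set after that, and its outcome depends on this choice. The results in this part were singled out because the effect of OPN, tested as a difference, was not the same with and without FGF2 or in STIA and naive fibroblasts.

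The interaction passed for 7723 genes, and of 8609 genes called with FGF2, 5644 were called back toward or past the unstimulated level in the joint samples, 489 were called further and 900 were called opposite to FGF2 against unstimulated cells. Picking genes by a large FGF2 change favours a smaller second value, so genes were also picked at 2-fold on 1 FGF2 and 1 control library and measured against the others, where the median change in the joint samples was 37.5%, 42.0% and 37.2% of that with FGF2. The tables argue against RNA of FGF2-treated cells diluted with RNA of other naive cells as the whole cause, since 810 genes in the joint samples lay beyond the FGF2, OPN and unstimulated groups alike (472 higher, 338 lower). Dilution as a part of the cause cannot be excluded by that count. Without the 100 most abundant genes 99.8% of 2665 interaction genes of at least 2-fold stayed called. Their own counts stay the same in that run and they were picked by a large called interaction. The run could therefore hardly have ended a call, and it does not decide whether a few abundant genes took the counts. The tables argue against FGF2 replicate 2 as the whole cause, since 96.2% of 2685 interaction genes of at least 2-fold stayed called the same way without it. That OPN may restrain the response of the cells to FGF2 stays open as a hypothesis, as does a culture difference between the joint and FGF2 samples, which the labels do not let the data separate.

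In naive fibroblasts immediate early, inflammatory and glycolysis genes fell with OPN. Of 58 members tested 40 fell in naive cells and 1 of these fell in STIA cells. A positive difference of the OPN effect was called for 35 of the 40. Those 40 were picked on naive libraries that also enter the difference, which favours positive values. Of all genes 2.2% passed for OPN in STIA cells and 31.7% in naive cells, so 1 fallen member is weak evidence of absence. As lists only immediate early genes stayed called by camera with an estimated correlation. Inflammatory and glycolysis genes did not (adjusted p = 0.119 and 0.0546 in naive cells, 0.0908 and 0.0686 for the difference). Under both other scalings of the libraries 100% of the 40 fallen members stayed called lower. These scalings differed little in this comparison. The median log2 fold change of all genes was 0.004 with TMM, 0.008 with DESeq2 size factors and 0.018 with library totals alone. They could therefore hardly have ended a call, and the result covers the choice among these scalings only. Fewer immune cells among the OPN samples are argued against for the glycolysis and immediate early members with the largest losses. The highest of 28 immune markers in unstimulated naive cells, Cd14, averaged 5.85 CPM while 13 members lost more than 100 CPM. Of the inflammatory members only Cxcl5 (116 CPM) was among these 13, while Cxcl1 lost 38.2, Ccl7 37.3 and Il6 3.97 CPM. The comparison does not decide the question for the inflammatory members. Handling at harvest cannot be told apart from the group, because all 3 OPN libraries lay below all 15 other libraries for 9 of 11 immediate early genes and the labels do not say which samples were handled together. A response to OPN that may be absent or weaker in STIA cells stays open beside it.

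In STIA fibroblasts OPN moved genes against the difference between STIA and naive cells: 285 of 327 called genes went the opposite way, in comparisons that share the unstimulated STIA libraries with opposite sign (r -0.60 across genes, -0.49 in simulations without change). The unstimulated STIA libraries that both comparisons share are argued against as the whole cause, since with different libraries the correlation across genes was -0.45, -0.40 and -0.43 with 1 of them in the STIA difference and -0.41, -0.44 and -0.31 with 2. Naive RNA or cells in the STIA OPN samples cannot be excluded, because 8.9% of the 327 genes lay outside the range between unstimulated STIA and naive samples, and 18.1% of 210 genes departed by more than 3 SE from 1 common share of naive unstimulated RNA (23.2% of 259 genes for naive OPN RNA), where at most 5% would fit and more than 20% for both sources would argue against it as the whole cause. Over the 210 genes the median share was 32.4%, with quartiles of 19.6% and 45.4%. Over the 259 genes it was 17.2%, with quartiles of 6.7% and 32%. In naive unstimulated, STIA unstimulated and STIA OPN samples Thbs4 averaged 1958, 651 and 1338 CPM and Prelp 253, 115 and 215 CPM. Dkk3, at 513, 203 and 206 CPM, and Col2a1, at 158, 52.4 and 51.9 CPM, stayed at the STIA level. A share as large as that of Thbs4 would not leave them there, but these picked genes say nothing against a smaller share. The homeobox genes Hoxc13 (1.86, 10.5 and 5.75 CPM), Hoxc11 (1.77, 7.56 and 4.21 CPM) and Shox2 (3.36, 16.9 and 9.3 CPM) moved part of the way back. They too were picked after their values were seen. OPN may have moved STIA cells towards the naive state. A smaller share of naive material, a different make-up of the STIA cell samples or a condition common to the 3 unstimulated STIA samples may have given the pattern or added to it. These values do not tell them apart, and the make-up of the cell samples was not tested. The count behind the pattern fell to 38, 81 and 218 without STIA unstimulated replicates 1, 2 and 3. It fell to 76, 44 and 112 without STIA OPN replicates 1, 2 and 3.

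Among called genes with a mean of at least 5 CPM over the libraries compared, the largest positive values of the interaction of FGF2 and OPN were Steap4 8.19, Cxcl5 7.85, Kng1 7.83, Hp 7.43 and C3 7.31, and the largest negative values were Nefm -6.57, Cnr1 -6.43, Tslp -5.77 and Serpinb2 -5.69. Mmp10 had a fitted value of -6.85 that depends on the prior count and is no bound, since it averaged 0.091 CPM in unstimulated naive cells, at the floor of 3 counts; Steap4, at 0.14 CPM with FGF2, and Tslp, at 0.214 CPM in unstimulated naive cells, were near it, so their values carry that limit too. The list medians were 2.21 for immediate early, 2.05 for complement, 1.85 for sublining, 1.49 for pericyte and smooth muscle, 1.28 for interferon, 0.88 for inflammatory, 0.88 for matrix and 0.74 for glycolysis genes, and -1.15 for ERK targets, -1.28 for osteopontin and its receptors, -0.93 for cell cycle and -0.56 for p53 and senescence genes, of which only immediate early genes and osteopontin and its receptors stayed called with an estimated correlation. The limit on handling of the OPN libraries at harvest holds for the immediate early genes here too.

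The difference of the OPN effect between STIA and naive fibroblasts passed for 3364 genes. Among those with a mean of at least 5 CPM over the libraries compared, the largest positive values were C3 3.95, Fos 3.61, Nr4a1 3.27, Fosb 3.25 and Cxcl1 3.12, and the largest negative values Adcyap1r1 -3.35, Cck -3.32, Bc1 -3.14, Serpinb9b -2.94 and Car8 -2.92. The list medians were 1.24 for immediate early, 0.98 for Schwann, 0.80 for inflammatory, 0.76 for glycolysis, 0.60 for sublining, 0.51 for stress response and 0.26 for matrix genes, and -0.47 for FGF ligands and receptors, -0.44 for osteogenic, -0.40 for contractile, -0.36 for osteopontin and its receptors, -0.30 for cholesterol and -0.24 for p53 and senescence genes, of which only immediate early genes stayed called with an estimated correlation. That call carries the limit on handling of the naive OPN libraries at harvest.

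Other splits of the same libraries were run for each count of genes. With 3 against 3 libraries there are 10 splits, so the share of splits as large as the real one cannot be under 0.1, and only the counts are given. The real split alone (1 of 10) gave 8609 genes for FGF2, 4783 for OPN, 7513 for both, 5550 for STIA against naive cells, 327 for OPN in STIA cells, 8804 for both against FGF2, 8522 for both against OPN and 9278 for FGF2 against OPN, and the highest other counts were 0, 0, 0, 0, 0, 10, 0 and 1. For the interaction 1 of 100 relabellings, the real one, reached 7723 genes. Relabelling removes the OPN effect with and without FGF2 alike, so this share cannot tell an interaction from any effect of OPN. The highest other, 7594, exchanged the OPN labels of all FGF2-treated libraries at once and so tests the sum of the OPN effects, and the next gave 6223. For the difference of the OPN effect 1 of 100, the real one, reached 3364 genes, with 2568 as the highest other. The same limit holds there, so neither share excludes chance as the source of a difference.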

How the results depend on the processing

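The alternatives in this part were planned. No called list or named gene changed direction in any setting run. Values that were not called changed sign 79 times for lists and 4 times for named genes. With library totals alone the balance of higher and lower genes turned over in some comparisons. FGF2 plus OPN against unstimulated cells went from 3573 higher and 3940 lower to 5253 and 2414. The difference of the OPN effect went from 1776 positive and 1588 negative to 1556 and 1744. Across settings other than left-out libraries the number of genes changed ran from 7018 to 8768 for FGF2, 4431 to 4932 for OPN, 6267 to 7667 for both factors, 5066 to 6075 for STIA, 7234 to 8805 for both against FGF2, 7194 to 8637 for both against OPN, 7469 to 9454 for FGF2 against OPN, 6614 to 7767 for the interaction and 3174 to 4093 for the difference of the OPN effect. Of 162 gene counts 154 stayed within 1.5 times the count reported and 8 moved, each of them for OPN in STIA cells. Of 18838 values of named genes 18327 kept their side of the threshold, 403 lost and 104 gained a call and 4 moved. With the replicate number as a replicate block the counts were 8509, 4601, 7366, 5409, 292, 8676, 8399, 9182, 7587 and 3225 in the order of the comparisons in the methods. Thinned to the smallest total, OPN in STIA cells gave 298 genes, and what more depth would add was not tested.

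OPN in STIA cells gave 948 genes with no filter on low counts, 626 by DESeq2 and 1367 with only these groups in the model, which left 13843 genes tested as well as fewer libraries; the cause was not tested for any of them. Leaving out 1 library gave 38 to 218 genes for it, and 7956 to 8373, 3619 to 4184, 6571 to 7510, 4416 to 4886, 8025 to 8760, 7690 to 8345, 8615 to 9026, 7104 to 7911 and 2650 to 3280 for the others in the same order.

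The number of lists called by camera was 9, 10, 9, 12, 13, 10, 11, 12, 12 and 13. With the estimated correlation it was 3, 2, 1, 1, 3, 0, 4, 2, 2 and 1, and by fry 25 for FGF2, 16 for both factors, 4 for OPN in STIA cells, 24 for both against FGF2, 21 for both against OPN, 26 for FGF2 against OPN and 20 for the interaction; fry does not compare a list with other genes. Where camera with the estimated correlation called 0 lists, 8 had an unadjusted p below 0.05.

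At an adjusted p below 0.01 the genes higher and lower in both were 550 and 647 for FGF2 and OPN, 463 and 483 for OPN and the joint treatment, 998 and 1104 for FGF2 and STIA, 386 and 442 for OPN and STIA, and 3 and 1 for OPN in naive and STIA cells; fewer genes pass the stricter threshold by its construction.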

Other observations

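The genes in the next paragraph were chosen after their values were seen, as were the partings in the last paragraph that gave FGF2 2 control libraries; the other partings there were planned before their result.

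Some genes stood in the joint samples beyond the unstimulated, FGF2 and OPN samples of naive cells. The STIA samples were not part of that choice. Serpina3n, an acute-phase protease inhibitor, averaged 116 CPM with FGF2 plus OPN, against 7.6 CPM in unstimulated, 3.51 CPM in FGF2 and 6.77 CPM in OPN samples. The brain-derived neurotrophic factor receptor gene Ntrk2 averaged 21.2 CPM against 1.47, 3.99 and 1.72 CPM, and the lipoxygenase gene Alox12 averaged 16.8 CPM against 2.86, 1.5 and 3.25 CPM. Bmf, a BH3-only promoter of apoptosis, averaged 17.7 CPM against 3.35, 2.8 and 2.49 CPM, and Plppr3 averaged 50.7 CPM against 10.5, 11.5 and 5.48 CPM. Trim66 went the other way, at 1.92 CPM against 14.6, 9.83 and 12.1 CPM.

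Fgf2 itself averaged 67.6 ± 4.69 CPM in unstimulated naive cells, 424 ± 28.1 CPM with FGF2, 128 ± 43.2 CPM with OPN and 256 ± 26.8 CPM with both factors (SD, n = 3 each). It averaged 155 ± 15.5 CPM in unstimulated STIA cells and 112 ± 11.6 CPM in STIA cells with OPN (SD, n = 3 each). Mitochondrially encoded genes took 0.374% to 0.867% of counts, lowest in the library numbered 3 in 5 of 6 groups.

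Of the genes called both with FGF2 and in STIA, 1526 were higher and 1660 lower in both and 674 went opposite ways, in comparisons that share the 3 unstimulated naive libraries. With those shared, r was 0.50, and unchanged groups in simulations gave 0.51, so this r carries no weight by itself. A hypothesis is that unstimulated STIA fibroblasts carry part of the response to FGF2, which predicts a positive correlation when the comparisons share no control library. With different control libraries the correlations across genes were 0.44, 0.44 and 0.43 with 1 of them for FGF2, and 0.42, 0.41 and 0.42 with 2. The values needed were there, which suggests but does not establish such a response. Genes are not independent replicates, and a condition common to the 3 unstimulated naive samples stays open.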
